A study of Danio rerio with 24 samples.

How the data were processed

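Zebrafish embryos of the transgenic line Tg(XlEef1a1:GFP)s854, in which GFP marks digestive organs formed from endoderm, were dissociated at 2, 3, 4 and 6 days post fertilization (dpf). The cells were sorted by fluorescence into a GFP+ and a GFP- fraction, called gates here. Total RNA from each sorted sample was amplified to cDNA, labelled with biotin and hybridized to an Affymetrix zebrafish array. Each of the 8 groups, a gate at an age, held 3 arrays, so that 24 arrays were used. Per the labels, each replicate gave a GFP+ and a GFP- sample.

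The deposited values are a score per probe set and array. The authors' processing notes name RMA, which gives values on a log scale. In the table every array had a median of 0 and a standard deviation (SD) of 1 over its 15617 probe sets, so a difference of 1 equals 1 array SD. The log base and the scaling step are not given in the sources used here. The plan written before the data were examined had assumed log2 values, and no fold changes are given for this reason. Arrays have no read depth, and their number limits the precision.

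Of the 15617 probe sets, 115 controls were left out and 15502 were tested without a filter on signal. The array annotation gave 1 gene symbol for 10795 probe sets, several for 135 and none for 4572. Symbols were updated through gene identifiers for 10711 probe sets, which changed 1 symbol. This gave 8793 genes, each represented by its brightest probe set, and 619 of these symbols were placeholders for clones or loci. Among 641 genes with more than 1 called probe set over the 4 ages, 50 had probe sets called in both directions.

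A linear model with 8 group means was fitted to every probe set with limma 3.58.1 in R 4.3.3. The moderated tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. GFP+ cells were compared with GFP- cells at each age and over the 4 ages with equal weights. Change with age was tested between 6 and 2 dpf in each gate and for each adjacent pair of ages in GFP+ cells. An F test asked whether the GFP+ minus GFP- difference varied with age, and a single contrast compared it between 6 and 2 dpf. Standard errors (SE) use the spread shared by all 8 groups, since a group of 3 arrays gives little information on its own. The spread of each probe set was moderated toward that of all probe sets, with prior degrees of freedom 3.6. Compared by exact permutation alone, 3 arrays against 3 cannot give a p under 0.1, so each single-gene call rests on the model.

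The labels number the replicates 1 to 3 within each gate and age. Residuals of same-numbered GFP+ and GFP- arrays correlated between -0.079 and 0.312 (mean 0.081), and 4 of the 12 pairs were over 0.1. Pairs with other numbers averaged -0.039. The model was fitted without a term for the pair, and pairing was tried as an alternative. Nothing in the sources used here says whether replicates came from separate clutches. If they did not, the p-values measure the spread between these samples only.

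Before the data were examined, 30 gene lists were fixed for digestive organs, cell processes, signalling pathways and the other cell types of the embryo. Some genes stand in more than 1 list. For each list the called members were counted, both over all probe sets and adjusted over the list alone. The list was tested against all other genes with camera at a preset correlation of 0.01, with camera at an estimated correlation, and by itself with fry. Named genes follow a rule of the same date. It takes the 15 largest differences each way over the 4 ages with the same sign at every age, and the 6 largest each way at each age. It also takes the 10 largest each way for the difference between 6 and 2 dpf, the 12 largest in GFP+ and the 8 largest in GFP- cells between these ages, and the 4 largest at each step. Placeholder symbols were passed over, and 1 of them stood among the 15 largest higher over the 4 ages. Members of a list may be named as examples.

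Alternatives planned were pairing terms, quantile normalization, array weights, a trend with a robust prior, the mean of a gene's probe sets, fits on the 6 arrays of a comparison alone, and leaving out each array. The planned minimum of 5 on the log2 scale and the planned fold threshold have no meaning on the score scale and were not run. A mean score of at least 0 and a difference of at least 1 array SD were used in their place, chosen after seeing the data. The lists under quantile normalization and the removal of the third GFP+ array at 6 dpf, which correlated least with its group, together with the third GFP- array at 4 dpf, which had the highest liver and zymogen levels of its group, were also added then. The model was tested on simulated data with the same layout and 15502 probe sets. A true difference of 1 array SD was recovered for 91% of 67 probe sets between the gates at 2 dpf, and for 70.1% in the comparison of that difference between 6 and 2 dpf. At 0.5 array SD the shares were 47.8% and 20.9%. In each simulation only 67 probe sets differed by 0.5, 67 by 1 and 66 by 2 array SD. In the data 17% of probe sets were called between the gates at 2 dpf. The adjusted p depends on that share, and each simulated probe set had the same spread in all groups. So the shares recovered do not give the sensitivity in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The control probe set for EGFP read between -0.696 and -0.176 on every array, near the floor, and was not used to judge the sort.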

Results

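Gene expression was profiled on 24 arrays of sorted zebrafish cells, with 3 arrays for each of the GFP+ and GFP- gates at 2, 3, 4 and 6 dpf. The title of the series names development of the gastrointestinal tract, and the sort sets cells of the digestive organs against the rest of the embryo. All values are scores in units of 1 array SD. Arrays of 1 group correlated between 0.893 and 0.983 over all probe sets (median 0.967), and GFP+ with GFP- arrays at a median of 0.832. The first component of the arrays held 46.9% of the variance and parted the gates, and the second held 18.2% and followed age. The third GFP+ array at 6 dpf stood apart, with a mean correlation of 0.897 with its group mates against at least 0.925 in the other groups. The GFP- arrays at 4 dpf differed widely in digestive transcripts: the median score of the zymogen list was 1.803, 0.218 and 2.502 on the 3 arrays, and that of the liver list 0.866, 0.614 and 2.224.

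**Figure D1:**
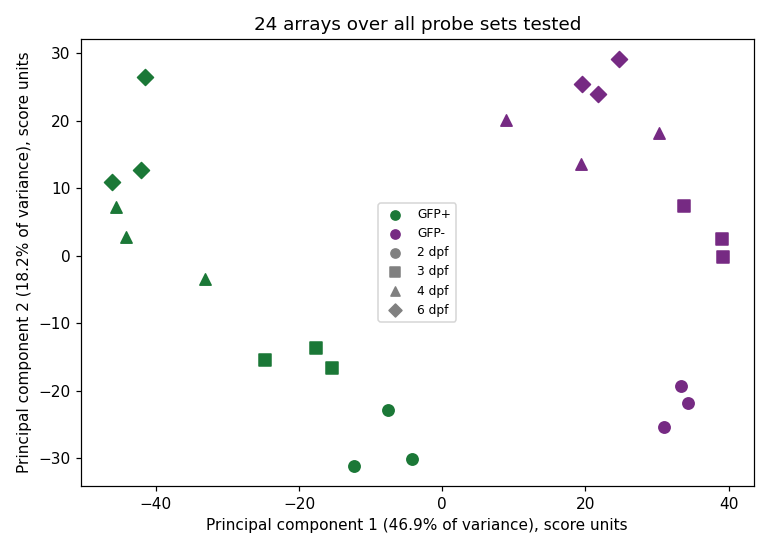
Each point is 1 of the 24 arrays on the first 2 principal components of the 15502 probe sets tested, in score units, with colour for the gate and shape for the age. GFP+ arrays lie on the negative side of component 1, which holds 46.9% of the variance, and GFP- arrays on the positive side.

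The first comparison asks which genes differ most between the gates in the mean over all ages. The genes named have the same sign at every age, but they need not be called at each age. Liver transcripts led: the glycogen phosphorylase gene pygl was higher in GFP+ cells by 2.25 ± 0.15 array SD (SE, n = 12 arrays per gate). The fibrinogen chain gene fgg was higher by 2.22 ± 0.19, fgb by 2.13 ± 0.18 and fga by 1.98 ± 0.16. The plasma protein genes ambp and vtnb were both higher by 2.13, with SE 0.21 and 0.16. The urate oxidase gene uox (2.11 ± 0.17), the kininogen gene kng1 (2.06 ± 0.15) and the apolipoprotein gene apom (2.01 ± 0.19) were also higher. So were the coagulation factor gene f5 (1.98 ± 0.15), cyp8b1.1 of bile acid synthesis (1.96 ± 0.14) and the transporter gene slco1d1 (1.94 ± 0.11). The aquaporin gene aqp12 (1.94 ± 0.17), the oxidase gene hao1 (1.94 ± 0.12) and itih2 (1.91 ± 0.17) closed the set of 15.

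The 15 genes furthest on the GFP- side over the 4 ages include genes of the eye and brain. The lysozyme gene lyz, expressed in white blood cells, differed by -2.65 ± 0.21 array SD (n = 12 arrays per gate). The photoreceptor transducin genes gngt2a (-2.44 ± 0.12), gngt1 (-2.33 ± 0.12) and gngt2b (-2.14 ± 0.14) were lower, as were the cone opsin genes opn1sw1 (-2.19 ± 0.14) and opn1sw2 (-2.05 ± 0.15). The forebrain and eye regulators foxg1b (-2.32 ± 0.10), six7 (-2.14 ± 0.15) and six6b (-1.95 ± 0.12) were lower too. The creatine kinase genes ckmt2a (-2.27 ± 0.15) and ckbb (-1.94 ± 0.13) and the synaptophysin gene sypb (-1.93 ± 0.12) followed. The parvalbumin gene pvalb5 (-2.17 ± 0.10), guk1b (-2.08 ± 0.16) and acsl6 (-2.03 ± 0.09) completed the 15.

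At an adjusted p under 0.05, 9055 of 15502 probe sets differed between the gates over the 4 ages, 5844 higher and 3211 lower in GFP+ cells. After quantile normalization 7627 differed, 4067 higher and 3560 lower, so the share called higher was 64.5% as deposited and 53.3% then. Among the 860 that differed by at least 1 array SD the larger side turned round, with 368 higher and 492 lower. At all 4 ages separately, 805 probe sets were higher, where 9.6 would be shared if the ages were independent, and 579 were lower, against 2.3. Each probe set has 1 estimate of spread for all ages, so some of this excess follows by construction. Another 83 were higher at 1 age and lower at another.

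The lists for digestive organs were higher in GFP+ cells over the 4 ages by camera, and none of these calls held with an estimated correlation. Of the 35 measured liver genes 33 were higher and 0 lower, and the same numbers were adjusted over the list alone (adjusted p = 2.75e-12; adjusted p = 0.233 with an estimated correlation). Of 24 complement and coagulation genes 21 were higher and 2 lower, and adjusted over the list alone also 21 and 2 (adjusted p = 7.59e-07; adjusted p = 0.27 with an estimated correlation). The exceptions were cfd (-0.80 ± 0.13), complement factor D, and c6.2 (-0.30 ± 0.06). Of 34 lipoprotein and lipid handling genes 27 were higher and 3 lower, as when adjusted over the list alone (adjusted p = 0.000166; adjusted p = 0.207 with an estimated correlation). The apolipoprotein genes apoba (1.88 ± 0.16) and apoc2 (1.86 ± 0.11) were higher, and the brain fatty acid binding protein gene fabp7a was lower (-1.91 ± 0.10). Of 26 xenobiotic and steroid metabolism genes 23 were higher and 2 lower, and adjusted over the list alone 23 and 2 (adjusted p = 3.06e-06; adjusted p = 0.151 with an estimated correlation).

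Pancreas and gut transcripts were also on the GFP+ side. Of 17 zymogen genes of the exocrine pancreas 16 were higher, as when adjusted over the list alone, among them the pancreatic disulfide isomerase gene pdia2 (1.64 ± 0.17), cpa4 (1.57 ± 0.18) and prss1 (1.45 ± 0.15). Their camera adjusted p was 0.00032, and adjusted p = 0.387 with an estimated correlation. Of 26 genes of the intestinal epithelium 20 were higher and 2 lower, or 21 and 2 adjusted over the list alone (adjusted p = 0.000284; adjusted p = 0.383 with an estimated correlation). The claudin gene cldn15la (1.59 ± 0.16) and apoa4b.1 (1.56 ± 0.12) were higher, and gpa33a was lower (-0.64 ± 0.18). Of 23 endoderm transcription factor genes 18 were higher and 1 lower, or 20 and 1 adjusted over the list alone (adjusted p = 2e-04; adjusted p = 0.151 with an estimated correlation). The largest were gata6 (1.36 ± 0.08), nr5a2 (1.3 ± 0.09) and foxa1 (1.11 ± 0.10). Genes of the secretory pathway of the endoplasmic reticulum (ER) moved together, with 45 of 47 higher, or 46 adjusted over the list alone (adjusted p = 5.24e-11; adjusted p = 0.207 with an estimated correlation). Its examples are the chaperone gene dnajc3a (1.23 ± 0.13) and the translocon gene tram1 (0.96 ± 0.10).

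Endocrine pancreas genes split: of 11 measured, 4 were higher and 5 lower, as when adjusted over the list alone. The list was not called by camera (adjusted p = 0.196), while fry called it lower (adjusted p = 0.000266). The hormone genes ins (1.15 ± 0.17), sst2 (0.85 ± 0.16) and gcga (0.57 ± 0.12) were higher in GFP+ cells in the mean over the 4 ages. For gcga this did not hold at each age, since at 6 dpf its score was higher in GFP- cells. For sst2 the difference between the gates also fell between 2 and 6 dpf. The transcription factor genes neurod1 (-1.84 ± 0.09) and isl1a (-1.27 ± 0.10), which neurons also express, were lower. At 6 dpf the list was called lower, with 4 lower and 0 higher, or 5 and 1 adjusted over the list alone (adjusted p = 0.0168; adjusted p = 0.329 with an estimated correlation).

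Of the lists for other tissues, those of neurons, retina and lens, epidermis and connective tissue had most of their members lower in GFP+ cells. Of 34 neuron genes 31 were lower and 0 higher, as when adjusted over the list alone (adjusted p = 2e-20; adjusted p = 0.0962 with an estimated correlation). Of 34 retina and lens genes 27 were lower and 1 higher, also when adjusted over the list alone (adjusted p = 2.26e-15; adjusted p = 0.0962 with an estimated correlation). Of 42 epidermis genes 28 were lower and 6 higher, with the same counts adjusted over the list alone (adjusted p = 2.02e-07; adjusted p = 0.332 with an estimated correlation). The keratin genes krt1-19e (-1.50 ± 0.17) and krt15 (-1.35 ± 0.18) were lower, and krt8 (0.51 ± 0.12) and krt18a.1 (0.47 ± 0.11), which simple epithelia express, were higher. Of 37 cartilage, bone and connective tissue genes 21 were lower and 3 higher, unchanged when adjusted over the list alone (adjusted p = 7.59e-07; adjusted p = 0.151 with an estimated correlation). Skeletal muscle had 17 of 36 genes lower and 4 higher, equal to the counts adjusted over the list alone (adjusted p = 0.000725; adjusted p = 0.288 with an estimated correlation).

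Among blood cell and vessel markers, members went both ways. Of 29 leukocyte genes 14 were lower and 6 higher, as when adjusted over the list alone (adjusted p = 0.00408; adjusted p = 0.383 with an estimated correlation). The actin regulator gene coro1a (-1.34 ± 0.11) was lower with lyz, whereas the myeloperoxidase gene mpx was higher (1.34 ± 0.10). Of 14 vascular endothelium genes 5 were lower and 1 higher, in either count (adjusted over the list alone 5 and 1), with fli1 at -1.09 ± 0.15 (adjusted p = 0.0163; adjusted p = 0.207 with an estimated correlation). Of 21 genes of the gut wall mesenchyme and its muscle 10 were lower and 6 higher, also adjusted over the list alone (adjusted p = 0.01; adjusted p = 0.207 with an estimated correlation). The smooth muscle actin gene acta2 was lower (-0.90 ± 0.07), and so was elavl3 (-1.67 ± 0.11), a neuron gene on that list. Of 43 genes that respond to heat or dissociation stress 18 were lower and 4 higher, the counts adjusted over the list alone included (adjusted p = 0.00125; adjusted p = 0.447 with an estimated correlation). Fry did not call the stress list (adjusted p = 0.0559).

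**Figure D2:**
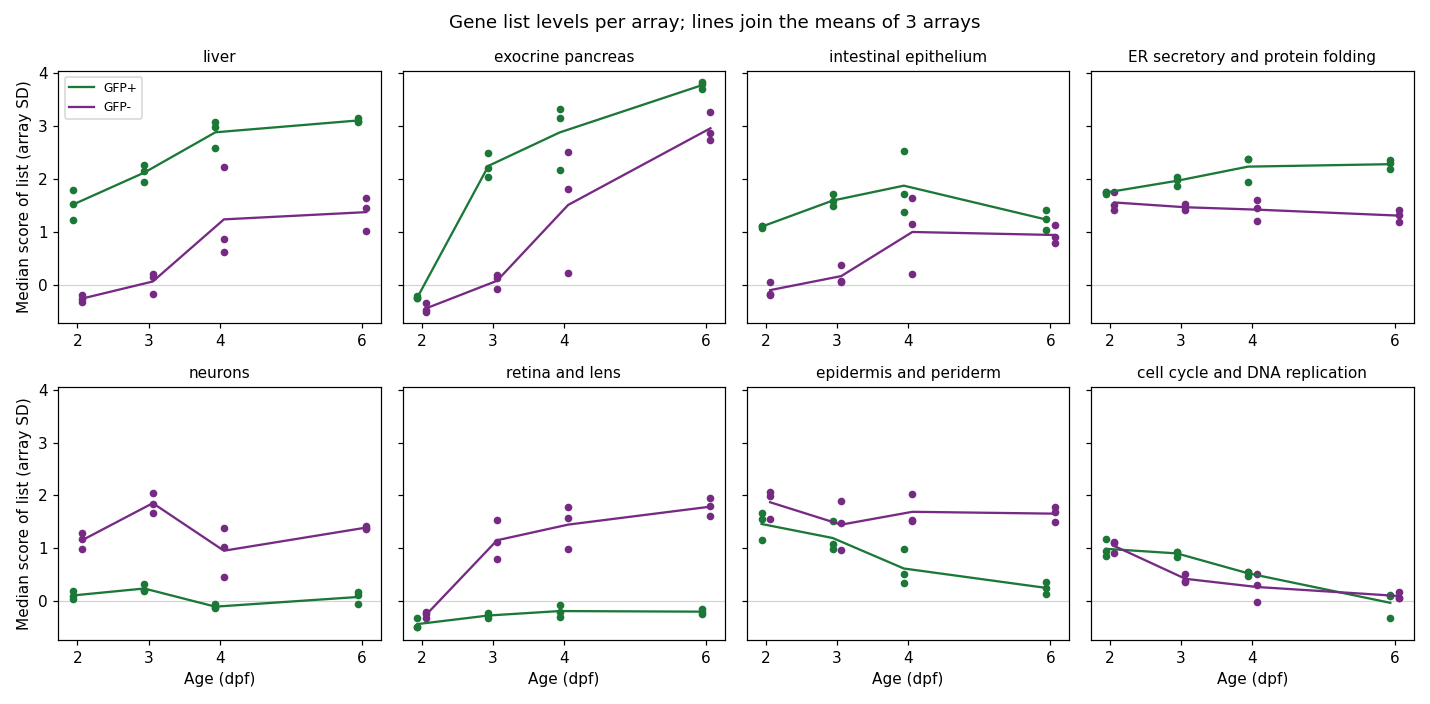
Points give the median score of a gene list on each array, in array SD, against age in dpf, and lines join the means of 3 arrays for GFP+ and GFP- cells. The liver list lies above 1.2 on every GFP+ array, and the zymogen list climbs from below 0 at 2 dpf in both gates.

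At single ages, fabp10a, the liver fatty acid binding protein gene, led at 2 dpf (2.91 ± 0.24, n = 3 arrays per gate), before lgals2b (2.80 ± 0.29) and the trypsin gene prss1 (2.72 ± 0.30). The fin fold gene and2 (-2.29 ± 0.22) and the neuron gene elavl3 (-2.03 ± 0.22) were lower. At 3 dpf the apolipoprotein genes apoa4b.2 (2.42 ± 0.27) and apobb.1 (2.39 ± 0.26) were higher, and the cone phosphodiesterase gene pde6c was lower (-2.68 ± 0.27). At 4 dpf a2m2f (2.17 ± 0.39) and apoba (2.16 ± 0.32) were higher, with GFP- scores that varied there (SD 1.27 and 0.93, n = 3), and guk1b was lower (-2.91 ± 0.33). At 6 dpf shbg (2.41 ± 0.33), slc37a4a (2.31 ± 0.21), ahsg1 (2.31 ± 0.19) and the complement gene c3a.6 (2.31 ± 0.29) were higher, and opn1sw1 was lower (-3.1 ± 0.29).

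The number of probe sets that differed between the gates was 2638 at 2 dpf (1497 higher and 1141 lower in GFP+ cells) and 4103 at 3 dpf (2244 and 1859). At 2 dpf a sign of RNA quality also parted the gates: the GAPDH control score toward the 3' end minus that toward the 5' end was 0.755, 0.399 and 0.527 on the GFP+ and 0.236, 0.269 and 0.266 on the GFP- arrays, so the genes and lists of that age differ along with it. The number was 4696 at 4 dpf (2946 and 1750) and 5915 at 6 dpf (3603 and 2312). After quantile normalization it was 2523 at 2 dpf (1271 and 1252), 4019 at 3 dpf (2073 and 1946), 4348 at 4 dpf (2316 and 2032) and 4864 at 6 dpf (2509 and 2355). The larger side turned round for differences of at least 1 array SD at 2 dpf (256 and 323), 3 dpf (465 and 609) and 6 dpf (556 and 820), and at 6 dpf for a mean score of at least 0 (1993 and 2003). With only the 6 arrays of 4 dpf in the model the count there was 2831. Zymogen genes called higher numbered 5 of 17 at 2 dpf, 12 at 3 dpf, 15 at 4 dpf and 4 at 6 dpf, against 5, 12, 16 and 4 adjusted over the list alone. Their camera adjusted p was 4.88e-07 at 3 dpf and 0.00075 at 4 dpf, where adjusted p = 0.258 and adjusted p = 0.465 with an estimated correlation. The list was not called at 2 dpf (adjusted p = 0.0883) or 6 dpf (adjusted p = 0.0946). Retina and lens genes lower in GFP+ cells numbered 5 of 34 at 2 dpf, 27 at 3 dpf, 26 at 4 dpf and 27 at 6 dpf. The counts adjusted over the list alone were 5, 27, 27 and 27. That list was called at each age by camera, the weakest at 2 dpf (adjusted p = 0.0175; adjusted p = 0.489 with an estimated correlation and 0.269 by fry). At the other ages the adjusted p was 3.7e-17, 1.29e-19 and 1.89e-16, with adjusted p = 0.0656, 0.0753 and 0.143 with an estimated correlation.

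With an estimated correlation 3 of the lists were still called at 2 dpf, where the GAPDH scores part the gates, all at an adjusted p of 0.0313. Of the 23 endoderm transcription factor genes 13 were higher and 0 lower, or 15 and 0 adjusted over the list alone. Of the 34 neuron genes 25 were lower, or 29 adjusted over the list alone. Of the 37 cartilage, bone and connective tissue genes 21 were lower in both counts, that adjusted over the list alone included. At 3, 4 and 6 dpf and over the 4 ages, 0 lists were called that way by camera, where 8, 6, 4 and 7 had an unadjusted p under 0.05. Fry called 18, 18, 15 and 23 lists in these 4 comparisons.

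The next comparison asks which differences between the gates changed with age. From 2 to 6 dpf the difference grew by 2.54 ± 0.37 array SD for the carboxypeptidase gene cpn1, 2.50 ± 0.36 for the fibronectin gene fn1b and 2.29 ± 0.41 for c3a.6 (n = 3 arrays in each of 4 groups). It also grew for the chitinase gene chia.6 (2.25 ± 0.28) and the plasma protein gene ahsg1 (2.21 ± 0.26). Of these c3a.6, chia.6 and ahsg1 were near the floor in both gates at 2 dpf. The largest decrease was in s100z (-3.28 ± 0.49), a calcium binding protein gene, whose score went from 2.01 ± 0.76 to -0.09 ± 0.15 (SD, n = 3) in GFP+ cells. The cone genes pde6c (-3.13 ± 0.39), opn1sw1 (-2.96 ± 0.40) and opn1mw1 (-2.81 ± 0.36) followed, and their GFP- scores rose from near the floor. The glucagon gene gcga turned round (-2.69 ± 0.33), from 3.1 ± 0.09 to 1.46 ± 0.44 in GFP+ and from 1.47 ± 0.26 to 2.52 ± 0.28 in GFP- cells.

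By the F test the difference between the gates varied with age for 1077 probe sets. Between 6 and 2 dpf it differed for 1306, with 548 moving up and 758 down. Without the third GFP+ array at 6 dpf the count was 1744, with 891 up and 853 down, so the larger side turned round. With array weights it was 3571, with 2026 up and 1545 down. The GAPDH difference given for 2 dpf moved with this comparison: at 6 dpf it was -0.128, -0.096 and 0.272 on the GFP+ and 0.848, 0.242 and 0.35 on the GFP- arrays. The 3' score itself was 1.561, 1.684 and 1.851 on the GFP+ arrays at 2 dpf and 0.519, 0.42 and 0.274 at 6 dpf. On the GFP- arrays it was 2.478, 2.456 and 2.427, then 2.851, 2.617 and 2.825. Differences can be compressed at a lower level, so RNA quality cannot be told apart here from the level of GAPDH.

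ER secretory genes moved up in this comparison in 23 of 47 cases and down in 0, or 33 and 0 adjusted over the list alone (adjusted p = 2.94e-16; adjusted p = 0.203 with an estimated correlation). In GFP- cells alone ER secretory genes fell in 11 cases and rose in 1, or 17 and 1 adjusted over the list alone (adjusted p = 0.0134; adjusted p = 0.603 with an estimated correlation). The unfolded protein response gene xbp1 gained 1.21 ± 0.26 and sec61a1b 1.34 ± 0.22. Retina and lens genes moved down in 20 of 34 cases, or 22 adjusted over the list alone (adjusted p = 1.02e-17; adjusted p = 0.11 with an estimated correlation). Endocrine genes moved down in 6 of 11 cases and up in 0, or 7 and 2 adjusted over the list alone (adjusted p = 0.000758; adjusted p = 0.203 with an estimated correlation). Beside gcga these were sst2 (-2.41 ± 0.46), neurod1 (-1.25 ± 0.26), isl1a (-1.11 ± 0.28), insm1b (-1.10 ± 0.21) and sst1.1 (-0.89 ± 0.27). Pharyngeal endoderm, thyroid and swim bladder genes moved down in 11 of 32 cases, or 14 down and 3 up adjusted over the list alone (adjusted p = 0.0018; adjusted p = 0.362 with an estimated correlation). Among them were cldn3c (-2.45 ± 0.45), pax1b (-2.26 ± 0.47) and the Hedgehog ligand gene shha (-2.13 ± 0.30). Epidermis genes moved down in 10 of 42 cases, or 11 down and 1 up adjusted over the list alone (adjusted p = 8.7e-06; adjusted p = 0.548 with an estimated correlation). Fry did not call the epidermis list in this comparison (adjusted p = 0.123).

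Intestinal genes moved down in 8 of 26 cases and up in 2, or 11 and 3 adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.596 with an estimated correlation). The difference shrank for cldn15la (-2.18 ± 0.45), fabp2 (-2.16 ± 0.43) and lgals2b (-2.06 ± 0.41). For gpa33a it moved by -2.37 ± 0.50, from 0.44 ± 0.35 at 2 dpf, where it was not called, to -1.93 ± 0.35 at 6 dpf. Complement genes moved up in 8 of 24 cases and down in 1, or 11 and 3 adjusted over the list alone (adjusted p = 0.00489; adjusted p = 0.548 with an estimated correlation). Xenobiotic and steroid metabolism genes moved up in 5 of 26 cases, or 9 adjusted over the list alone (adjusted p = 0.000399; adjusted p = 0.34 with an estimated correlation). Cartilage, bone and connective tissue genes moved up in 7 of 37 cases, or 13 up and 1 down adjusted over the list alone (adjusted p = 8.28e-05; adjusted p = 0.294 with an estimated correlation). Stress response genes were called down with 2 of 43 cases down and 1 up, or 4 and 1 adjusted over the list alone (adjusted p = 0.000159; adjusted p = 0.548 with an estimated correlation). Fry did not call the intestinal, complement and stress response lists in this comparison (adjusted p = 0.29, 0.123 and 0.155). The liver list went both ways, with 7 of 35 up and 5 down in either count, that adjusted over the list alone included, and was not called (adjusted p = 0.575). The tyrosine aminotransferase gene tat gained 1.94 ± 0.38, and the difference shrank for fabp10a (-2.51 ± 0.35), whose scores at 6 dpf were near the top of the scale in both gates.

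**Figure D3:**
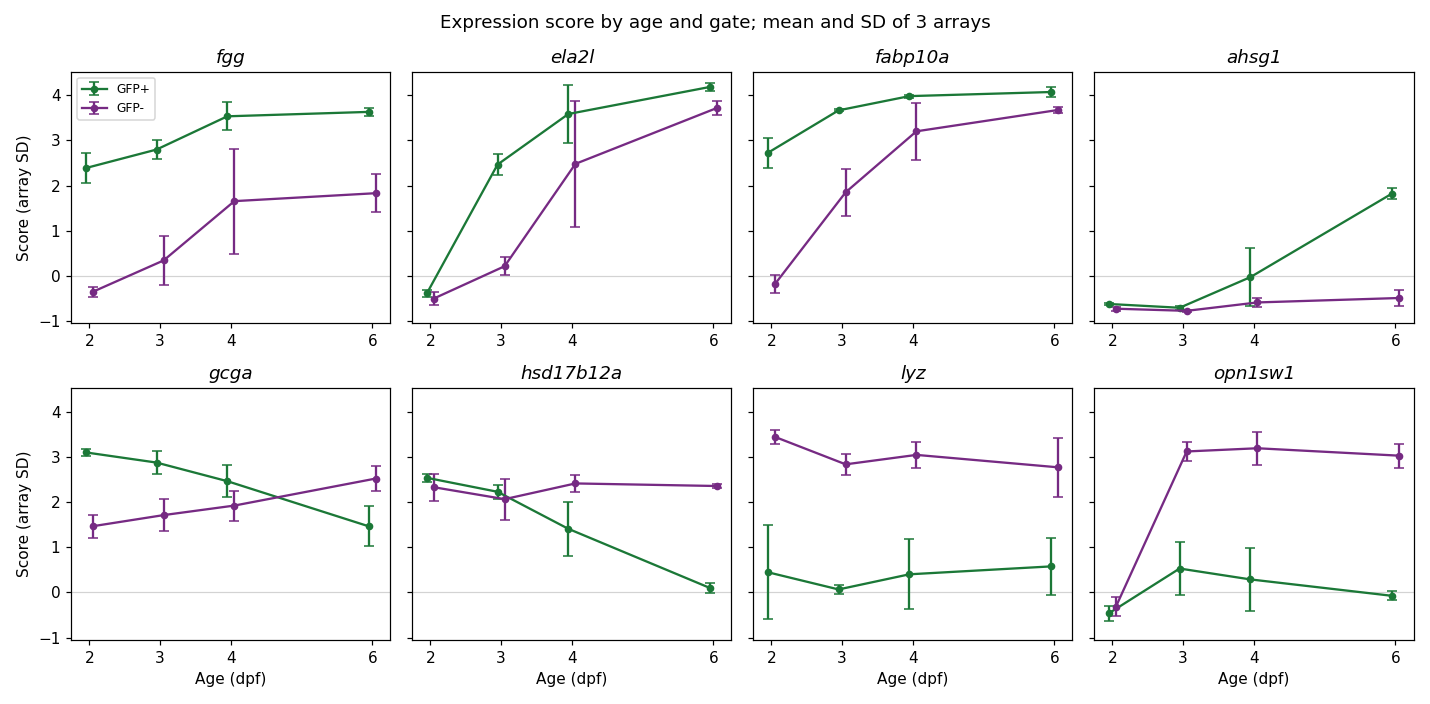
Mean score and SD of 3 arrays, in array SD, for 8 genes against age in dpf in GFP+ and GFP- cells. The elastase gene ela2l rises in both gates, ahsg1 reaches 1.82 at 6 dpf in GFP+ cells, and gcga falls in GFP+ cells while it rises in GFP- cells.

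Within GFP+ cells, digestive enzyme genes of the pancreas were among those with the largest rises in score between 2 and 6 dpf. Their list went from -0.24, near the floor, to 3.77, where array maxima were 4.541 to 4.779, so the sizes and order of these rises are uncertain at both ends. The elastase genes ela2l (4.57 ± 0.42, n = 3 arrays per age), ela2 (4.49 ± 0.39) and ela3l (4.2 ± 0.34) rose, as did the chymotrypsin genes ctrl (4.27 ± 0.40) and ctrb.2 (4.11 ± 0.41). The amylase gene amy2a (4.19 ± 0.42), the phospholipase gene pla2g1b (4.18 ± 0.47) and the lipase gene cel.1 (4.1 ± 0.39) rose too. So did cela1.5 (4.08 ± 0.34), cpa5 (4.04 ± 0.42), c6ast3 (3.96 ± 0.40) and the mitochondrial uncoupling gene ucp1 (4.08 ± 0.22). The steroid and fatty acid enzyme gene hsd17b12a fell by 2.44 ± 0.23, agr2 of secretory epithelia by 2.42 ± 0.26 and svopl by 2.36 ± 0.39. The ribonucleotide reductase gene rrm2l (-2.32 ± 0.23), the keratin gene krt1-19e (-2.28 ± 0.33), gpa33a (-2.25 ± 0.35) and the fast muscle myosin gene mylpfa (-2.18 ± 0.27) fell as well.

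In this comparison 3434 probe sets were called, 1422 rising and 2012 falling. Without the third GFP+ array at 6 dpf there were 3631, with 1891 rising and 1740 falling, so here too the larger side turned round. With array weights there were 5783, with 3124 rising and 2659 falling. The GAPDH scores given for the GFP+ arrays at 2 and 6 dpf part these same arrays, all 3 at 6 dpf lying below all 3 at 2 dpf. The 3' score fell between these arrays too, so RNA quality cannot be told apart here from the level of GAPDH. All 17 zymogen genes rose, also adjusted over the list alone (adjusted p = 1.17e-18; adjusted p = 0.159 with an estimated correlation). Of 35 liver genes 31 rose and 0 fell, or 33 and 0 adjusted over the list alone (adjusted p = 4.32e-19; adjusted p = 0.159 with an estimated correlation). Examples are fetub (3.05 ± 0.35), tat (2.95 ± 0.27) and tdo2a (2.86 ± 0.29). Complement genes rose in 18 of 24 cases, or 20 adjusted over the list alone (adjusted p = 3.16e-11; adjusted p = 0.159 with an estimated correlation). ER secretory genes rose in 24 of 47 cases, or 28 up and 1 down adjusted over the list alone (adjusted p = 7.14e-09; adjusted p = 0.292 with an estimated correlation). Lipoprotein genes rose in 15 of 34 cases and fell in 1, or 17 and 2 adjusted over the list alone (adjusted p = 9e-07; adjusted p = 0.159 with an estimated correlation).

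Cell cycle genes fell: 45 of 49 were lower at 6 than at 2 dpf and 0 higher, or 47 adjusted over the list alone (adjusted p = 9.21e-25; adjusted p = 0.159 with an estimated correlation). The nucleotide enzyme gene dut fell by 1.92 ± 0.20 and rrm1 by 1.91 ± 0.31. On the third GFP+ array at 6 dpf the median score of this list was -0.325, against 0.124 and 0.103 on the other 2. Epidermis genes fell in 23 of 42 cases, in the count adjusted over the list alone too (adjusted p = 1.87e-06; adjusted p = 0.51 with an estimated correlation). Stress response genes fell in 16 of 43 cases and rose in 2, or 18 and 2 adjusted over the list alone (adjusted p = 0.00135; adjusted p = 0.704 with an estimated correlation). The median score of that list was 0.223 on the third GFP+ array at 6 dpf and 0.924 and 0.905 on the others. Endocrine genes fell in 4 of 11 cases, also adjusted over the list alone (adjusted p = 0.0498; adjusted p = 0.42 with an estimated correlation): isl1a, insm1b, gcga and sst2.

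In GFP- cells the same ages differed in digestive enzyme and eye genes, many of them near the floor at 2 dpf. The chymotrypsinogen gene ctrb.1 rose by 4.36 ± 0.32 (n = 3 arrays per age), ela2l by 4.22 ± 0.42, ela2 by 4.18 ± 0.39 and prss1 by 4.17 ± 0.30. The genes pde6c and fabp10a both rose by 3.86, with SE 0.27 and 0.24. The globin gene hbae3 fell by 2.53 ± 0.60, the decorin gene dcn by 1.98 ± 0.18, mylpfa by 1.85 ± 0.27 and the limb and fin mesenchyme gene prrx1b by 1.82 ± 0.23. Of 15502 probe sets 2854 were called, 1360 rising and 1494 falling. Without the third GFP- array at 2 dpf there were 2014, with 1008 rising and 1006 falling. With all arrays 658 of those called differed by at least 1 array SD, 472 rising and 186 falling, so the larger side turned round in both.

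With an estimated correlation 6 lists were called in GFP- cells between 6 and 2 dpf. Zymogen genes rose in 16 of 17 cases, also adjusted over the list alone (adjusted p = 2.65e-22; adjusted p = 0.0484 with an estimated correlation). Lipoprotein genes rose in 15 of 34 cases and fell in 1, or 19 and 1 adjusted over the list alone (adjusted p = 5.23e-09; adjusted p = 0.0484 with an estimated correlation). Retina and lens genes rose in 23 of 34 cases, or 24 adjusted over the list alone (adjusted p = 2.65e-22; adjusted p = 0.048 with an estimated correlation). Cell cycle genes fell in 43 of 49 cases, or 45 adjusted over the list alone (adjusted p = 7.92e-22; adjusted p = 0.0484 with an estimated correlation). Skeletal muscle genes fell in 23 of 36 cases and rose in 2, or 26 and 3 adjusted over the list alone (adjusted p = 1.33e-09; adjusted p = 0.0484 with an estimated correlation). Cartilage, bone and connective tissue genes fell in 21 of 37 cases, or 22 adjusted over the list alone (adjusted p = 4.62e-09; adjusted p = 0.0484 with an estimated correlation). The liver list rose in 26 of 35 cases, or 28 adjusted over the list alone (adjusted p = 5.28e-21; adjusted p = 0.105 with an estimated correlation). Intestinal genes rose in 16 of 26 cases and fell in 2, or 17 and 2 adjusted over the list alone (adjusted p = 4.69e-08; adjusted p = 0.287 with an estimated correlation).

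Part of the change between 2 and 6 dpf was shared by the gates. In both, 447 probe sets rose, where 124.8 would if the gates were independent, and 776 fell, against 193.9. The same estimate of spread per probe set serves both gates, so some of this excess follows by construction. Only 71 went opposite ways, against 313.6.

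The last comparisons follow GFP+ cells from age to age. Between 2 and 3 dpf ela2l (2.86 ± 0.42, n = 3 arrays per age), cpa5 (2.83 ± 0.42), crp3 (2.70 ± 0.29) and ela2 (2.60 ± 0.39) rose, and the muscle genes mylpfa (-1.78 ± 0.27) and tpma (-1.40 ± 0.23) fell. Between 3 and 4 dpf pla2g1b (2.62 ± 0.47), ctrb.2 (2.41 ± 0.41), ucp1 (2.28 ± 0.22) and cyp2ad2 (2.28 ± 0.28) rose, and svopl (-1.86 ± 0.39) and gpa33a (-1.78 ± 0.35) fell. Between 4 and 6 dpf ahsg1 (1.85 ± 0.19) and tat (1.76 ± 0.27) rose. The respiratory chain genes ndufa4b (-1.88 ± 0.16) and cox4i1l (-1.53 ± 0.28), the mitochondrial creatine kinase gene ckmt1 (-1.75 ± 0.33) and the lectin gene mbl2 (-1.60 ± 0.25) fell.

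The first step had 128 called probe sets, 83 rising and 45 falling, and 58 to 153 when 1 array was left out. The second had 1068, 593 rising and 475 falling, or 995 with 452 and 543 after quantile normalization, 338 without the third GFP+ array at 4 dpf, and 218 with its 6 arrays alone. The third had 712, 244 rising and 468 falling, or 693 with 320 and 373 after quantile normalization, and 423 with 226 and 197 without the third GFP+ array at 6 dpf, where the larger side turned round. With only its 6 arrays in limma the third step had 0 called probe sets and 1592 at an unadjusted p under 0.05.

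**Figure D4:**
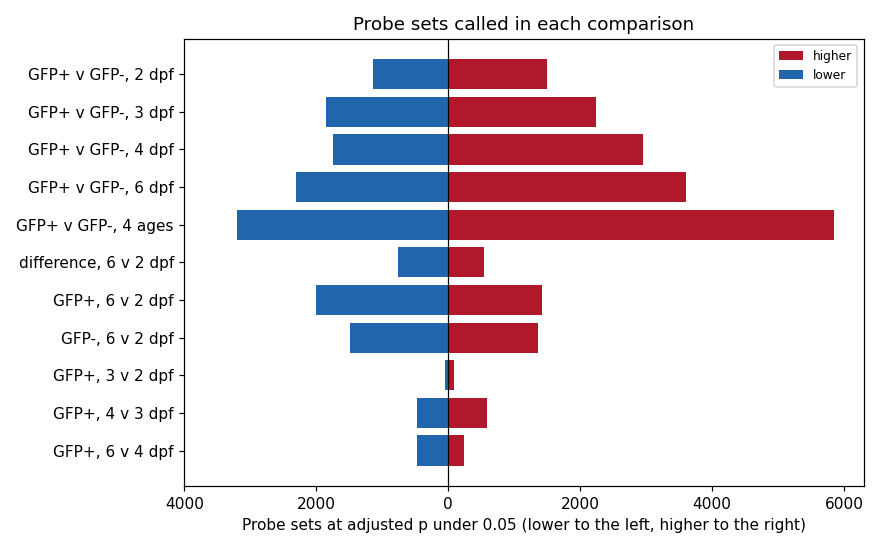
Bars give the number of probe sets called at an adjusted p under 0.05 in each comparison, higher to the right and lower to the left of 0. The count over the 4 ages is the largest, at 9055, and the step from 2 to 3 dpf the smallest, at 128.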

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

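The tests of splits of the arrays, of the excess of higher calls and of the third GFP+ array at 6 dpf were chosen after the results were seen, as was that of expression in GFP- cells. Those of scaling and of carry-over for the digestive transcripts were written before their values were seen.

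The difference between the gates depended on age, by a test of that difference, for 1077 probe sets over the 4 ages and for 1306 between 6 and 2 dpf. From 2 to 6 dpf it rose for cpn1 (2.54), fn1b (2.50), c3a.6 (2.29), upp2 (2.26), chia.6 (2.25), crp3 (2.21), ahsg1 (2.21), shbg (2.19), cyp2ad2 (2.15) and gda (2.14), in array SD. It fell for s100z (-3.28), pde6c (-3.13), opn1sw1 (-2.96), lad1 (-2.84), opn1mw1 (-2.81), opn1sw2 (-2.71), gcga (-2.69), pde6hb (-2.58), fabp10a (-2.51) and hsd17b12a (-2.47). For these 20 genes the sign held with each array left out and after quantile normalization. They were picked for the largest differences on these same arrays, so a change of sign was unlikely and this is no independent support.

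More probe sets were higher than lower in GFP+ cells over the 4 ages. More genes with large increases than with large decreases do not account for it, since among called probe sets that differ by at least 1 array SD 42.8% were higher, 41.5% to 44.5% with 1 array left out. The excess lay mostly, not wholly, among dim probe sets: of 3566 called with a mean score under 0, 78.7% were higher, against 55.3% of 5489 brighter ones, a gap of 23.4 points. This is consistent with small shifts of dim probe sets with the spread of the array distributions. Small increases of many weakly expressed transcripts stay open, since quantile normalization, after which 53.3% were higher, removes both alike.

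Digestive gland transcripts rose between 2 and 6 dpf in GFP- cells. Array scaling is argued against, since the median rise of the 52 zymogen and liver genes was 1.9 array SD as deposited and 1.93 after quantile normalization. RNA or cells carried over from the GFP+ gate may account for it: across these genes the rise in GFP- followed that in GFP+ cells (rho 0.49, r 0.6, two-sided permutation p = 0.00022 for rho, genes not being independent), and rho met the bound of 0.3 set in advance. But random lists of 52 genes gave a median rho of 0.49 and an upper limit of 0.7, a comparison added after rho was seen, and rho was 0.55 among the 17 zymogens and -0.07 among the 35 liver genes, so carry-over cannot be told apart from a change both gates share. Expression in cells of the GFP- gate also stays open: the zymogen difference between the gates at 6 dpf, 0.65, decides nothing, since the GFP+ level there (3.77, array maxima 4.541 to 4.779) is so high that differences can be compressed.

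The third GFP+ array at 6 dpf stood apart from its group. Its mean correlation with its group mates was 0.897 as deposited and 0.883 after quantile normalization. A linear shift or scaling of an array leaves this correlation unchanged, so it cannot test for a fault of that kind. The distribution of scores on this array did differ. Its upper quartile was 0.743 (mates 0.942 and 0.922) and its minimum -1.086 (mates -0.868 and -0.889). Quantile normalization removes such differences and did not raise the correlation, so they do not account for its low value. GFP- cells in that sample cannot be told apart from other reasons, since of the 3 lists at least 1 array SD lower in GFP+ than in GFP- cells at 6 dpf 2 lay above both mates: neurons at 0.177 (mates -0.063 and 0.118) and retina at -0.152 (-0.243 and -0.205), but epidermis at 0.132 (0.366 and 0.251). Fewer digestive gland cells in that sample stay open: 0 of 2 lists lay below the mates (zymogens 3.83, liver 3.145), but at a level that can hide a loss, while endoderm transcription factors (0.144, mates 0.408 and 0.645) and intestinal genes (1.04, mates 1.418 and 1.238) lay below both. Lower RNA quality of that sample stays open too, since its GAPDH score toward the 3' end minus that toward the 5' end, 0.272, lay above both mates (-0.128 and -0.096) but below the 0.848 of an array that did not stand apart. The EGFP control score of that array was -0.696 (mates -0.176 and -0.197). Its DsRed control score was low in the same way, at -0.733 (mates -0.387 and -0.341). Both lie near the floor, so the EGFP value is no sign of the sort or of RNA quality. The labels put this array in no group of its own, and no other biological explanation was tested.

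For the gates over the 4 ages, 1 of 100 splits drawn, the real one, gave as many calls (9055, highest other 5358), a share under 0.05. This test was chosen after the arrays were seen to part by gate, and its splits ignore the pairing. So it is no independent support. For the F test 2 of 100 gave as many as 1077 (highest other 2153), and for the difference between 6 and 2 dpf 2 of 100 gave as many as 1306 (highest other 2708), both shares under 0.05. That split of 2708 kept the true gates at 4 and 6 dpf, so that differences between the gates enter it. Splits that mix the gates at an age put those differences into the spread instead. So these 2 shares do not tell whether the change of the difference with age is chance. The other comparisons have 10 splits each, too few for a share under 0.05, and in each 1 split, the real one, gave the most calls. The real count and the highest other were 2638 and 2 at 2 dpf, 4103 and 9 at 3 dpf, 4696 and 440 at 4 dpf, and 5915 and 0 at 6 dpf. They were 3434 and 575 in GFP+ and 2854 and 0 in GFP- cells between 6 and 2 dpf, and 128 and 3, 1068 and 21, and 712 and 32 for the steps. Of the 10 splits between the gates at an age 4 part all 3 pairs, and the highest other among them was 0 at 2, 3 and 6 dpf and 15 at 4 dpf.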

How the results depend on the processing

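The removal of the third GFP+ array at 6 dpf together with the third GFP- array at 4 dpf, the minimum mean score, the minimum difference and the lists under quantile normalization were chosen after seeing the data. Counts are in the order 2, 3, 4 and 6 dpf and the 4 ages for the gates, then the F test, the difference and GFP+ and GFP- cells between 6 and 2 dpf, then the 3 steps. A difference of at least 1 array SD left 579, 1074, 1161, 1376, 860, 653, 654, 858, 658, 72, 167 and 101 probe sets, fewer by construction. Array weights gave 3960, 6445, 3617, 3571, 5783, 4663, 479, 3020 and 1698 for all but the gates at 4 and 6 dpf and over the 4 ages. For these counts the cause was not tested. By construction, fewer features were tested with the mean of each gene's probe sets (3654 at 6 dpf, 5426 over the 4 ages) and with a mean score of at least 0 (5481 over the 4 ages). Fits on 6 arrays alone gave 2831 at 4 dpf, 218 for the second step and 0 for the third by limma. The third had 1592 at an unadjusted p under 0.05. Such fits gave 4055 at 6 dpf and 2408 in GFP+ cells. They gave more calls than the main fit at 2 dpf (2837), at 3 dpf (4426), in GFP- cells (3894) and for the first step (146). Fewer samples alone therefore do not account for the lower counts. These fits also leave out the spread shared with the other groups. Without the third GFP+ array at 6 dpf and the third GFP- array at 4 dpf together the third step had 458. The cause was not tested. Leaving out 1 array gave 58 to 153 for the first step, 338 to 1565 for the second and 423 to 826 for the third. The first fell to 62 without the second GFP+ array at 2 dpf, and to 61 and 58 without the first and second at 3 dpf. The second fell to 508 and 486 without the second and the third GFP+ array at 3 dpf, and to 338 without the third at 4 dpf. The third fell to 423 without the third GFP+ array at 6 dpf. For the gates the ranges were 1970 to 2164, 3102 to 3943, 3707 to 4543, 4534 to 5984 and 8607 to 9554. They were 742 to 1564 for the F test, 925 to 1744 for the difference, 2579 to 3631 in GFP+ and 2014 to 2543 in GFP- cells, and 19 to 21 called lists over the 4 ages, the only list tests rerun this way. Each lone group of 2 arrays borrows its spread from the other groups.

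Pairing terms moved no count by over 1.5 times. Lists were run with the fixed pair term for the comparisons of the gates, not for age within a gate: 103 held and 1, ribosomal proteins at 4 dpf, lost its call (adjusted p = 0.0511). The random term had a correlation of 0.009. Of 134 called lists 9 held with an estimated correlation and 113 with fry. Over the 4 ages 0 of 20 held with an estimated correlation in camera, where 7 had an unadjusted p under 0.05, and fry called 23. The stress response list was not among those 23 (fry adjusted p = 0.0559). For the difference between 6 and 2 dpf camera called 14 lists and fry 8. With the mean of each gene's probe sets 129 held. After quantile normalization 126 held, 5 were no longer called and 3 turned round, all of the ribosomal protein list: the gates at 6 dpf (adjusted p = 2.15e-06 as deposited and 0.549 then), the difference between 6 and 2 dpf (4.86e-11 and 0.186) and GFP+ cells between these ages (1.29e-05 and 0.0278). The cause was not tested. Of 2344 recomputed values of named genes 2329 kept their call and direction and 0 turned round. The other 15 lost their call, for myhz1.3 in the first step, col2a1a in the second, and c6ast3 and cpa1 in the third. Named genes were picked for the largest differences on these same arrays. A lost call or a change of sign was therefore unlikely, and these counts are no independent support. The planned minimum of 5 on the log2 scale and the fold threshold were not run, since the scores have no such scale. On arrays, differences near the background signal are compressed and those near the top can be, which limits what dim and very bright probe sets show.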

Other observations

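Signalling lists had members on both sides of the sort. Over the 4 ages Bmp and Tgf-beta genes were lower in GFP+ cells in 8 of 30 cases and higher in 4, as when adjusted over the list alone (adjusted p = 0.0247; adjusted p = 0.332 with an estimated correlation). The activin subunit gene inhbaa differed by -1.57 ± 0.18 array SD (SE, n = 12 arrays per gate) and id1 by -0.71 ± 0.06. Fgf genes were lower in 7 of 19 cases and higher in 2, also adjusted over the list alone (adjusted p = 0.0352; adjusted p = 0.36 with an estimated correlation), with the Fgf target dusp6 at -0.58 ± 0.09. Hedgehog genes were higher in 5 of 14 cases and lower in 3 (adjusted over the list alone 5 and 3, adjusted p = 0.444), with the coreceptor gene boc at -1.19 ± 0.09 and ihha at 0.29 ± 0.05. Wnt genes were higher in 7 of 34 cases and lower in 6 (adjusted over the list alone 7 and 6, adjusted p = 0.278), with the Wnt inhibitor gene sfrp5 at 0.68 ± 0.09. Notch genes were higher in 5 of 26 cases and lower in 7 (adjusted over the list alone 5 and 7, adjusted p = 0.181), with the ligand gene dld at 0.64 ± 0.07. At 2 dpf, where the GAPDH scores part the gates, camera called 4 of these lists lower in GFP+ cells. Notch genes were lower in 5 of 26 cases and higher in 2, also adjusted over the list alone (adjusted p = 0.0235; adjusted p = 0.338 with an estimated correlation). Wnt genes were lower in 5 of 34 and higher in 1, in both counts (adjusted p = 0.0462; 0.413 with an estimated correlation; 0.0588 with the mean of each gene's probe sets). Bmp and Tgf-beta genes were lower in 5 of 30 and higher in 0, in both counts (adjusted p = 0.00091; 0.216 with an estimated correlation), and Fgf genes in 2 of 19 and 0, in both counts (adjusted p = 0.0235; 0.374 with an estimated correlation). Fry did not call the Wnt and Fgf lists at 2 dpf (adjusted p = 0.23 and 0.0817). Between 2 and 6 dpf in GFP- cells Notch genes fell in 8 of 26 cases and rose in 0, or 10 and 0 adjusted over the list alone (adjusted p = 0.00215; 0.15 with an estimated correlation). Wnt genes fell in 7 of 34 and rose in 1, in both counts (adjusted p = 0.04; 0.418 with an estimated correlation; 0.0585 after quantile normalization), and Bmp and Tgf-beta genes in 5 of 30 and 0, in both counts (adjusted p = 0.0312; 0.385 with an estimated correlation). In GFP+ cells between these ages camera did not call the Hedgehog, Wnt and Notch lists. Of 14 Hedgehog genes 2 fell and 0 rose (adjusted over the list alone 2 and 0, adjusted p = 0.77). Of 34 Wnt genes 5 fell and 1 rose (5 and 1, adjusted p = 0.612). Of 26 Notch genes 4 fell and 1 rose (4 and 1, adjusted p = 0.299), while fry called that list lower (adjusted p = 0.0326). Of the members of these lists shha fell by 1.53 ± 0.21 and sfrp5 by 1.88 ± 0.17. The Wnt target axin2 fell by 1.05 ± 0.17 and the hairy-related gene her9 by 1.26 ± 0.18. The receptor gene fzd8a rose by 0.42 ± 0.14 and the ligand gene dlc by 0.52 ± 0.12.

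Counts for the remaining lists are first those over the 4 ages. Pharyngeal endoderm, thyroid and swim bladder genes were lower in 9 of 32 cases and higher in 6, as when adjusted over the list alone (adjusted p = 0.0408; adjusted p = 0.387 with an estimated correlation). Without the third GFP+ array at 6 dpf the adjusted p was 0.0563, and without the second GFP- array at 4 dpf 0.0587. Ribosomal protein genes were higher in 32 of 72 cases and lower in 0, also adjusted over the list alone (adjusted p = 0.0537). Cell cycle genes were higher in 15 of 49 cases and lower in 7 (adjusted over the list alone 12 and 7, adjusted p = 0.889). Yolk syncytial layer and lysosome genes were higher in 13 of 26 cases and lower in 6 (adjusted over the list alone 13 and 6, adjusted p = 0.503), pronephros genes in 8 of 26 and 10 (8 and 10, adjusted p = 0.0923). Erythroid genes were higher in 6 of 22 cases and lower in 4 (6 and 4, adjusted p = 0.508), pigment cell genes in 7 of 15 and 3 (7 and 3, adjusted p = 0.889). Fry called the ribosomal protein list (adjusted p = 0.00332) and the yolk and lysosome list (adjusted p = 1.93e-05) higher. It called the pronephros list lower (adjusted p = 0.0021). Median and mean differed in sign for the endocrine, Hedgehog, Wnt, Notch, erythroid, pigment cell and pronephros lists, and for cell cycle genes both were positive while camera gave the lower side.

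Some of these lists were called in other comparisons by camera, and in none of those given here with an estimated correlation. Cell cycle genes were higher in GFP+ cells at 3 dpf in 19 of 49 cases and lower in 0, or 22 and 0 adjusted over the list alone (adjusted p = 0.000275; 0.437 with an estimated correlation). At 6 dpf 12 were lower and 0 higher, or 11 and 0 adjusted over the list alone (adjusted p = 0.000768; 0.558 with an estimated correlation; 0.092 by fry). The mean of the list medians there was -0.03 in GFP+ cells (SD 0.25, n = 3) and 0.1 in GFP- cells (SD 0.06, n = 3). The low median of the third GFP+ array, given above, lowers the GFP+ level here and in the next comparison. These 2 list tests were not rerun without that array. Between 6 and 2 dpf their difference was called down with 1 gene down and 0 up, or 0 and 0 adjusted over the list alone (adjusted p = 0.0153; 0.606 with an estimated correlation; 0.335 by fry). Ribosomal protein genes were higher at 4 dpf in 16 of 72 cases and lower in 0, or 12 and 0 adjusted over the list alone (adjusted p = 0.0289; 0.773 with an estimated correlation). At 6 dpf 44 were higher and 0 lower, or 53 and 0 adjusted over the list alone (adjusted p = 2.15e-06; 0.558 with an estimated correlation). Between 2 and 6 dpf 12 rose in GFP+ cells and 0 fell, in both counts (adjusted p = 1.29e-05; 0.704 with an estimated correlation). In GFP- cells 5 fell and 1 rose, or 4 and 1 adjusted over the list alone (adjusted p = 0.0114; 0.701 with an estimated correlation). Fry did not call this fall (adjusted p = 0.11). The difference moved up for 6 and down for 0, in both counts (adjusted p = 4.86e-11; 0.548 with an estimated correlation). Of these 5 ribosomal protein calls 0 held after quantile normalization.

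Pharyngeal endoderm, thyroid and swim bladder genes were lower at 4 dpf in 10 of 32 cases and higher in 1, in both counts (adjusted p = 0.00315; 0.263 with an estimated correlation). At 6 dpf 12 were lower and 4 higher, or 12 and 5 adjusted over the list alone (adjusted p = 0.00652; 0.378 with an estimated correlation). In GFP+ cells 9 fell between 2 and 6 dpf and 0 rose, or 10 and 0 adjusted over the list alone (adjusted p = 0.0375; 0.519 with an estimated correlation; 0.0647 with the mean of each gene's probe sets). Pronephros genes were lower at 2 dpf in 5 of 26 cases and higher in 3, or 8 and 3 adjusted over the list alone (adjusted p = 0.0243; 0.253 with an estimated correlation). Yolk syncytial layer and lysosome genes rose between 2 and 6 dpf in GFP+ cells in 10 of 26 cases and fell in 0, or 11 and 0 adjusted over the list alone (adjusted p = 0.000796; 0.159 with an estimated correlation). In GFP- cells 2 rose and 1 fell, in both counts (adjusted p = 0.0366; 0.385 with an estimated correlation). The difference of erythroid genes between 6 and 2 dpf was called up with 0 genes called, also adjusted over the list alone (adjusted p = 0.0386; 0.548 with an estimated correlation), and not called after quantile normalization. Fry did not call it either (adjusted p = 0.065).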
